A study of Homo sapiens with 2 samples.

How the data were processed

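HCT116 chromatin was fixed with 1% formaldehyde 72 h after plating, sonicated to about 300 to 400 bp and immunoprecipitated with an antibody to TRF2 (5 μg antibody per 100 μg chromatin), per the labels. There was 1 immunoprecipitated library and 1 input library. The peak list carries a name that mentions a control siRNA, whereas the labels mention no transfection, so whether the cells were transfected is not settled and they are described as labelled. The only values analysed were those of the peak list of the immunoprecipitated library; a read file or coverage track of the input was not used here. The submitters' processing notes name Bowtie2 2.3.2, MACS2 2.1.0, HOMER and ChIPseeker 1.36.0 and the builds GRCh38 and hg38. Their settings, the handling of duplicate and multiply aligned reads and any filter are not given in the sources used here.

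The peak list gives an interval, a summit and 4 values per peak. The deposited score column equals the whole part of 10 times the −log10 p. The deposited fold enrichment is a ratio of the immunoprecipitated pileup to the local background from the input, at the summit, on the scale of the authors' peak caller. The deposited −log10 p-value and −log10 q-value are the peak caller's, also at the summit. No −log10 p was below 3.01 and the −log10 q reached down to 0.230, so the authors' list was limited by p and not by q. These values were used only to describe, rank and filter peaks within the list.

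The depth behind each peak was recovered from its fold and p-value, taking MACS2's forms: fold is the pileup plus 1 over the background plus 1, and p is the upper Poisson tail. A whole-number pileup matched both values in 100% of peaks, with a tolerance of 0.001 on −log10 p and a largest residual of 0.00014. The background had a floor of 1.05, its genome-wide value, at which 7144 peaks (29.5%) lay. Its steps gave 0.564 immunoprecipitated reads per input read and a fragment length of 69 bp, equal to the smallest peak width and shorter than the sonicated fragments. The largest pileup was 138 reads, which is what 69 bp fragments allow with 1 read per position and strand. If the peak caller's default human genome size was used, the floor corresponds to about 41.1 M immunoprecipitated and 72.8 M input reads (M, 1e6 reads). Library totals are not given in the sources used here.

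Peaks were assigned by their summits to centromere bands, 2 Mb around them, variable heterochromatin and stalk bands, arms, unplaced sequences and the mitochondrial genome, with hg38 bands from circlize 0.4.16 and chromosome lengths from GenomeInfoDb 1.38.1 (R 4.3.3). Gene positions came from a RefSeq table of the same primary assembly (GRCh38.p14), which holds gene spans without strand or exons. Its 718 rows on unlocalized, patch or alternate sequences, listed under a chromosome's name with positions of those sequences, were recognised by their order in the table and left out, leaving 58961 genes. No genome sequence was used. The planned counts of telomere repeats, interstitial repeat loci, G-quadruplex motifs and transcription factor motifs, and the planned naming of peaks by their longest telomere repeat, were not analysed here. Promoters were replaced by windows of 3 kb around either gene end, matching on promoter GC by matching on gene-length decile, and assembled sequence outside unknown bases by whole chromosome lengths. Coordinates are 1-based.

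Shares of summits and counts of loci were compared with 1000 random placements of the same number of summits on the same chromosomes, two-sided; the smallest p is 0.002. Gene lists were compared with 10000 random lists, two-sided, with Benjamini-Hochberg adjustment over 20 lists. Both describe this list of peaks and compare no samples. Intervals are exact binomial (Clopper-Pearson) or exact Poisson at 95%. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Tested on simulated data, the recovery gave the right pileup in 100% of 4680 simulated peaks and accepted 0.043% of pileups that were not whole. The shuffle called 100% of sets planted at a ratio of 1.95 and 4.0% of random sets. The list test, over 19866 genes, called 100% of planted and 0.0% of random lists. In that simulation a larger share of genes held a summit than in the data (0.584% near an end), so its power does not carry over.

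The groups, the windows, the gene lists, the other settings listed last and the rule for named items were chosen before the data were examined. The rule takes the 10 peaks of highest fold on primary chromosomes, the 20 protein-coding genes with the strongest peak near an end (1 gene per peak), up to 10 miRNA genes, the loci of the series title, and from each list up to 4 members with a summit and 2 without, with ties going to the higher −log10 q and then the lower coordinate. The region classes, the count of chromosome ends within 20 kb, the arm densities, the counts of summits per gene, the pseudogenes, the densest windows, the settings restricted to arms, to strong arm peaks or to a q-value under 0.05, the setting without 1q and the shifts of the genes with a summit along the gene order were chosen after seeing the data. Settings fixed in advance as alternatives were a −log10 q of 5 or more, a fold of 5 or more, primary chromosomes alone, gene windows of 1 kb, protein-coding genes alone, intervals in place of summits, end windows of 20 and 500 kb, 50 kb around the title's loci, 10 kb around miRNA genes, summits anywhere in a gene, and lists without matching.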

Results

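TRF2, a shelterin protein that binds the double-stranded repeats of telomeres and is encoded by TERF2, was mapped by chromatin immunoprecipitation and sequencing in HCT116, a colorectal carcinoma cell line. The design had 1 immunoprecipitated library and 1 input library, the sonicated chromatin before immunoprecipitation. The data were the authors' list of 24258 peaks of the first over the second, on the human assembly hg38. With 1 library per group no difference between samples could be tested, and intervals here cover counting error only. The peaks were narrow, with a median width of 104 bp (range 69 to 3427 bp), and together covered 3533 kb. Their fold over the input background, the authors' value at each summit, had a median of 4.06 and a range of 1.43 to 41.0. The read pileup at the summit, recovered from the authors' fold and p-value, had a median of 11 reads (5 to 138), against a median input background of 1.69. At a q-value under 0.05 there were 19247 peaks (79.3%), and at a −log10 q of 5 or more there were 7288 (30.0%).

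The first comparison asked where in the genome the immunoprecipitated DNA exceeded its input. Most peaks lay at centromeres. The cytogenetic centromere bands, which hold 3.01% of the length of the 24 primary chromosomes, held 15201 peaks, or 62.7% of the list (exact binomial 95% interval 62.1% to 63.3%). Their density was 164 peaks per Mb (exact Poisson interval 161 to 166), against 1.22 per Mb (1.18 to 1.27) on the chromosome arms. A further 1704 peaks lay within 2 Mb of a centromere band and 1952 in the variable heterochromatin bands, a cytogenetic class. This class also holds genes such as TPTE on chromosome 21, and its repeat content was not analysed here. The arms, with 89.4% of the length, held 3378 peaks (13.9%).

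Centromeric peaks were not evenly shared between chromosomes. Chromosome 13 had 4133 peaks (36.1 per Mb, exact Poisson interval 35.0 to 37.3), of which 3317 fell in its centromere band. Chromosome 1 had 1986 centromeric peaks, chromosome 8 had 1515 and chromosome 20 had 1143. The centromere bands of chromosomes 14, 21 and X had 31, 19 and 74. Chromosome 21 still had 629 peaks, only 32 of them on its arm, so most lay in other bands outside the centromere band. Median fold over input was 4.16 in centromere bands and 3.76 on arms, and the median pileup was 12 and 7 reads. Among summits on primary chromosomes 68.2% lay in centromere bands, against 3.04% when the same numbers of summits were placed at random on the same chromosomes (ratio 22.4, two-sided permutation p = 0.002, the smallest that 1000 position shuffles can give). Satellite repeats differ in how completely the assembly holds them, and the treatment of reads with several equally good positions is not given in the sources used here. The density on chromosome 13 was 36.1 per Mb over its whole length and 1.11 per Mb on its long arm, which held 104 arm peaks.

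The 10 peaks of highest fold on primary chromosomes lay mainly in these regions. The strongest, with a fold of 41.0 and 83 reads, was in band q11 at the centromere of chromosome 4, from 51107171 to 51107579. Peaks of fold 36.8, 34.6 and 26.3 lay within 3 kb of each other in band p11.1 of chromosome 8, at 43239600 to 43240203, 43237605 to 43238161 and 43238625 to 43238770. A peak on chromosome 17 from 26567033 to 26567127, in the centromere band q11.1, had a fold of 34.0. The short arms of chromosomes 22 and 14 gave peaks of 30.7, 29.8 and 25.7, starting at 11212865 on chromosome 22, 16093334 on chromosome 14 and 10721054 on chromosome 22. Only 2 of the 10 were on arms outside these bands: chromosome X from 83748865 to 83749415, over the pseudogene TERF1P4 (fold 36.6, 74 reads), and chromosome 21 from 26288924 to 26289058, with no gene over it (fold 24.9).

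The next comparison concerned chromosome ends, where TRF2 is known to act. Of the 48 ends of the primary chromosomes, 24 had a peak within 20 kb, 10 at short-arm and 14 at long-arm ends. The strongest peak at each of these ends had its summit 10016 to 10593 bp from the first or last coordinate of the chromosome, whose outermost stretch is a run of unknown bases in hg38. Fold over input there ran from 5.03 to 13.2 (median 8.42), and all 24 had a −log10 q of 5 or more. The highest were 7p (13.2), 21q (11.5), 3p (11.2), 18p (11.1) and 1q (10.6). With 1 read per position and strand the pileup cannot pass 138 reads, which limits the fold at deep ends such as Xq (124 reads, fold 5.43). At 7p the pileup was 57 reads, so the order of ends by fold is not one of binding strength. The treatment of reads with several equally good positions is unknown here too, so whether the reads at an end came from that end is not settled. These peaks were deep in both libraries, with a median pileup of 82.5 reads over an input background of 10.4, whereas the 3349 other arm peaks had a median fold of 3.76 and a median pileup of 7. At some of the other 24 ends, the short arm of chromosome 14 among them, the run of unknown bases in hg38 is longer than 20 kb, so no peak could be listed there.

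**Figure D1:**
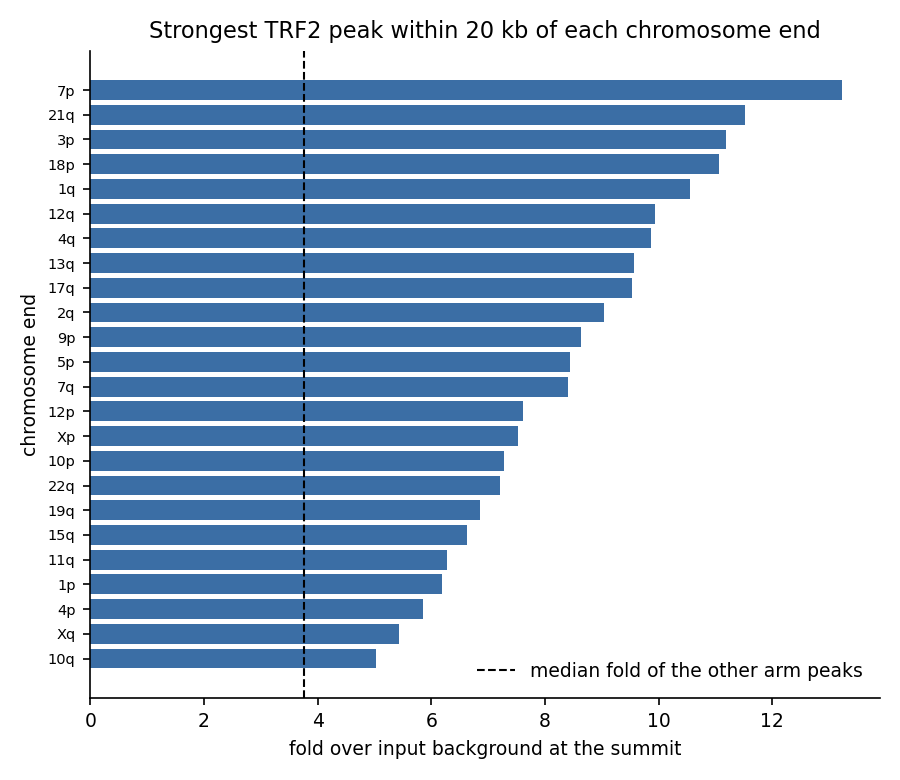
Fold over the input background (horizontal axis) of the strongest TRF2 peak within 20 kb of each of the 24 chromosome ends that had one (bars, 1 immunoprecipitated library). All bars, from 5.03 at 10q to 13.2 at 7p, lie above the dashed line at 3.76, the median of the other arm peaks.

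Shuffled summits reached 6.69 ends on average and at most 17, so 24 was outside their range (ratio 3.59, two-sided permutation p = 0.002, the smallest possible). With arm peaks alone, placed at random within their arms, the mean was 0.849 ends and the maximum 5. In the wider window fixed in advance, 59 summits (0.265%, exact interval 0.202% to 0.341%) lay within 100 kb of an end, 1.52 times the shuffled share (permutation p = 0.002). Within 500 kb the ratio was 0.878 (permutation p = 0.092), so no excess was detectable in that wider window. With arm peaks alone the ratio within 100 kb was 12.8. The 500 kb window was not run with arm peaks alone, so centromeric summits placed at random weigh on its ratio. Counts of telomere repeats within peaks were not analysed here.

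Peaks on the arms were sparse and uneven. Across 43 arms the density ran from 0.143 to 5.78 per Mb, with a median of 0.957. The long arm of chromosome 8 had 555 peaks, 5.46 times the density of the other arms (exact interval 4.98 to 5.98). The long arms of chromosomes 10 and 17 had 1.94 and 1.95 peaks per Mb, 1q had 2.17 (1.83 times the other arms), and the arms of X only 0.392 (Xp) and 0.288 (Xq). Within 8q the peaks lay from band q13 to the end (6.67 per Mb, against 1.32 nearer the centromere). Density was higher on 10q in q24 to q26 (3.35 against 0.890 per Mb) and on 17q in q21 to q25 (2.32 against 0.385 per Mb). Within these parts the peaks were uneven: 57 of 129 on 10q lay between 105 and 110 Mb, and 50 of 101 on 17q between 50 and 55 Mb. The 3 parts are present in extra copies in HCT116 by general knowledge of this line, and 1q is not among them. Among strong peaks 1q had 11.8 times the density of the other arms (exact interval 9.49 to 14.6). The arm class leaves out only the heterochromatin, stalk and centromere bands and 2 Mb around the latter, so peaks beside a heterochromatin band count as arm peaks. Where along 1q its peaks lay was not analysed here, so this density need not hold over the whole arm. The 8q peaks were shallow, with a median pileup of 6 reads, and 83.8% of them had an input background at its genome-wide minimum. No 8q excess was detectable among peaks with a −log10 q of 5 or more, where the ratio was 0.989 (exact interval 0.536 to 1.68), and was 1.42 (0.766 to 2.43) when 1q, which held 130 of the 407 strong arm peaks, was left out.

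**Figure D2:**
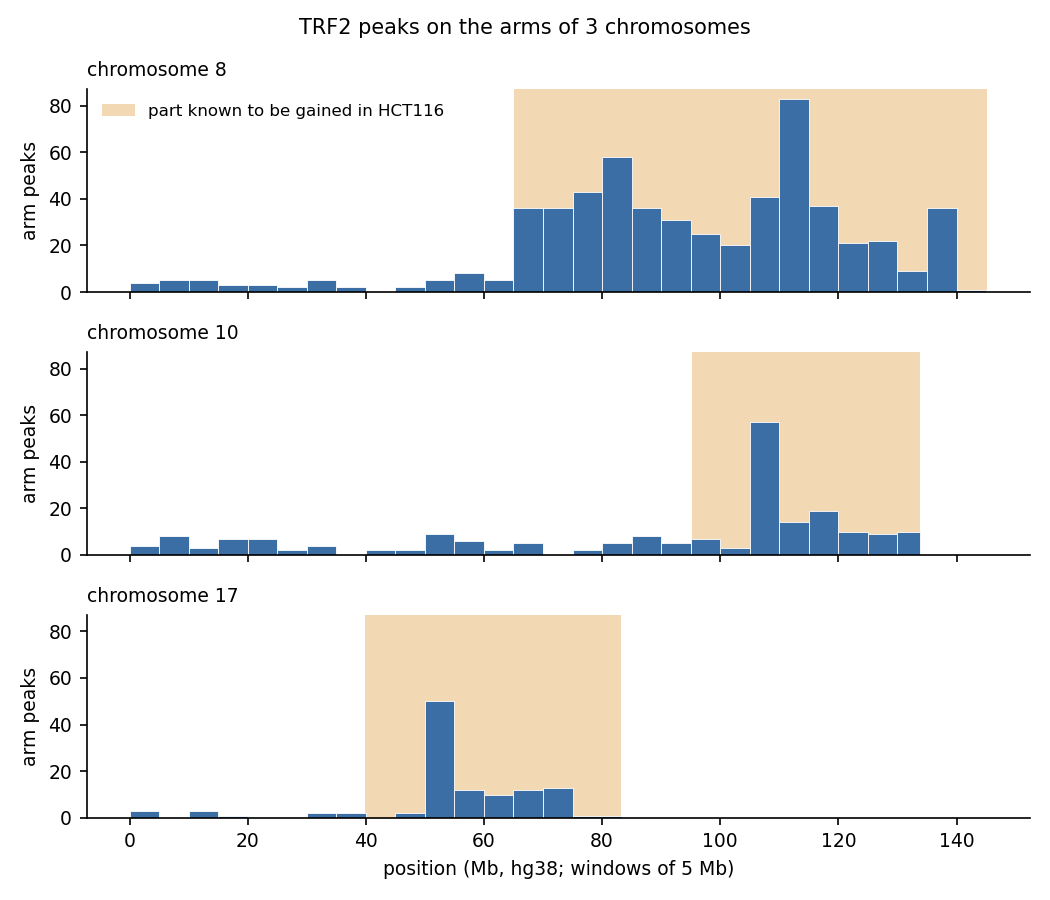
Number of TRF2 peaks on chromosome arms in windows of 5 Mb along chromosomes 8, 10 and 17 (vertical axis, peaks; horizontal axis, Mb on hg38), with the bands known to be gained in HCT116 shaded. Density inside the shaded bands was 6.67, 3.35 and 2.32 peaks per Mb, against 1.32, 0.890 and 0.385 in the rest of the same long arms.

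Peaks were depleted at genes. Of the summits on primary chromosomes, 583 (2.62%, exact interval 2.41% to 2.83%) lay within 3 kb of either end of an annotated gene, against 14.9% in shuffles (ratio 0.176, two-sided permutation p = 0.002, the smallest possible). Gene bodies held 9.64% of summits, against 52.4% in shuffles. Of 19866 protein-coding genes, 116 (0.584%) had a summit within 3 kb of an end, and for 19 of them it had a −log10 q of 5 or more. Much of this depletion went with the centromeric peaks: on the arms alone 11.8% of summits were near gene ends, against 15.6% in shuffles (ratio 0.752), and 51.6% in gene bodies, against 59.1% (ratio 0.873). Among the 407 strong arm peaks the share near gene ends was 19.7% against 17.4% (ratio 1.13, permutation p = 0.25), so no depletion at gene ends was detectable there. Gene bodies were still depleted in that set, with 42.3% against 59.8% (ratio 0.707, permutation p = 0.002).

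The 20 protein-coding genes with the strongest peaks near an end were led by TERF1 (fold 20.1), which encodes the shelterin protein TRF1. They were followed by HBB (13.2), the beta chain of adult hemoglobin, where 1 peak from 5224926 to 5226108 on chromosome 11 ran over one end of the gene. TERF2 itself had 10.7, CENPVL3 on the X chromosome 10.7 and ELMOD1 10.0, the latter 762 bp outside the gene. PAXBP1 (9.17), PACSIN2 (8.49), GK5 (8.07), NME8 (7.32) and SCGB1C2 (7.17) came next, then CYSLTR2 (6.83), a leukotriene receptor gene, ZMYM3 (6.80), FILIP1L (6.34) and SNX16 (5.93). LOC124907874 (5.87), PLA2G7 (5.86), PARP2 (5.15), which encodes a poly(ADP-ribose) polymerase of DNA repair, ANKRD66 (4.88), TRIM55 (4.88) and AFM (4.88) completed the set, the last 3 tied with ANGPT1 and kept by lower coordinate. Without strand in the gene table, an end near a peak was not assigned as a start or a terminus, and exons and introns were not used here.

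The series title links TRF2 to miR-181a-5p and to S100A10, a calcium-binding protein gene of the S100 family. Neither precursor locus of miR-181a nor S100A10 had a peak within 3 kb. On chromosome 1 the closest peak to MIR181A1 and MIR181B1 lay 38.9 kb and 39.1 kb away, at 198897981 to 198898049, inside the host transcript MIR181A1HG (198808003 to 198937429). It was weak, with a fold of 3.90, 7 reads at the summit and a −log10 q of 1.53. On chromosome 9 the closest peak to MIR181A2, MIR181B2 and MIR181A2HG was 1121 kb, 1122 kb and 1087 kb away (fold 2.97, −log10 q 0.488). For S100A10 (chromosome 1, 151982915 to 151993859) it was 2361 kb away (fold 3.41, −log10 q 0.811). Peaks of 6 or 7 reads were near the detection limit of the list, so weaker binding at these loci was not detectable at this depth.

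TERF2 had the most strong arm summits of any protein-coding gene. The gene (chromosome 16, 69355567 to 69386007) carried 9 separate summits of fold 5.50 to 12.2 and 15 to 35 reads, all with a −log10 q of 5 or more. TERF1 (chromosome 8, 73008864 to 73048123), which is outside the title and was added from the shelterin list, carried 8 summits of fold 4.82 to 20.1 and 11 to 53 reads, 7 of them strong. Input background was above its genome-wide minimum at 9 of 9 TERF2 summits and at 3 of 8 TERF1 summits. TERF1 pseudogenes elsewhere carried peaks too, at 4 of 7. Counting summits in a gene or within 3 kb of it, 102 protein-coding genes had at least 1 strong arm summit, 8 had 2 or more, and 4 had 4 or more.

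**Figure D3:**
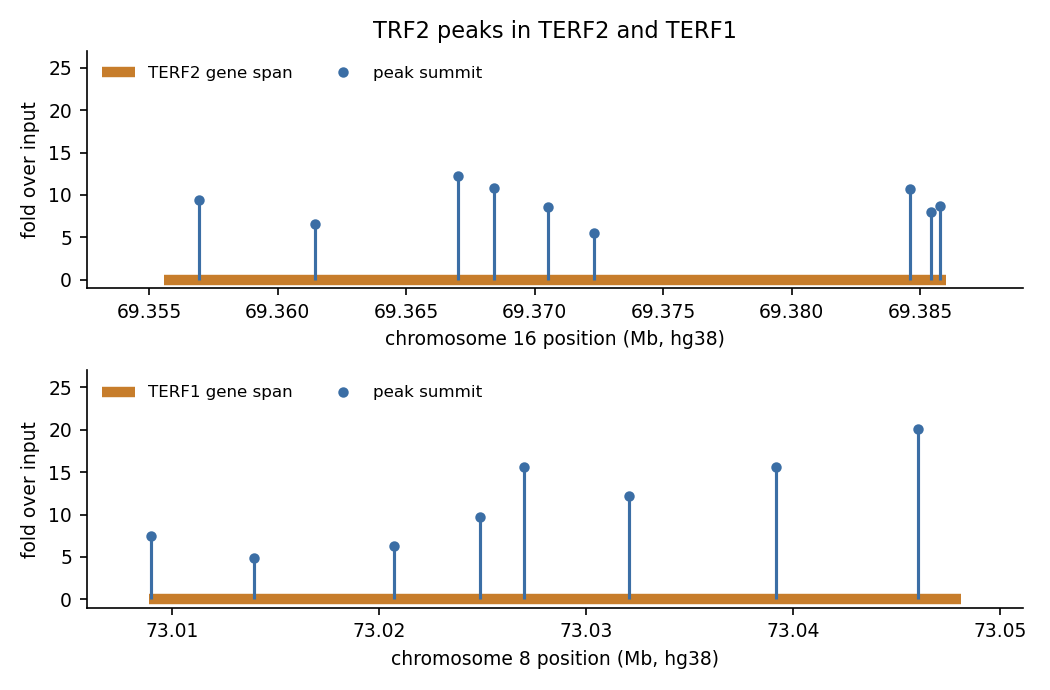
Fold over the input background (vertical axis) of each peak summit in TERF2 on chromosome 16 and TERF1 on chromosome 8 (horizontal axis, Mb on hg38; orange bars, gene spans). The 9 TERF2 summits reach 5.50 to 12.2 and the 8 TERF1 summits 4.82 to 20.1, spread over the length of each gene.

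Peaks at miRNA genes were few in general. Of 1913 annotated miRNA genes, 9 (0.470%, exact interval 0.215% to 0.891%) had a summit within 3 kb: MIR4719 (fold 3.41), MIR4273 (3.29), MIR4661 (3.29), MIR12136 (3.29), MIR4477B (3.19), MIR4524A and MIR4524B (one peak, 2.93), MIR4490 (2.93) and MIR8078 (2.78). Only MIR12136 and MIR8078 had a −log10 q of 5 or more, and both lay where the input was high (background 29.4 and 38.9). Shuffled summits met 76.4 miRNA genes on average (ratio 0.118, two-sided permutation p = 0.002, the smallest possible). With arm peaks alone, placed at random within their arms, the 9 genes were within the shuffled range (ratio 0.692, permutation p = 0.39).

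Gene groups fixed in advance were then compared with 10000 random lists of genes of like length, 20 lists in all, counting a gene where a summit lay within 3 kb of an end. The shelterin genes had 2 of 6 members with a summit, TERF1 and TERF2, against 0.0378 in random lists (permutation p of random lists, Benjamini-Hochberg adjusted p = 0.010). TERF2IP and TINF2 had none. Counting summits anywhere in the gene, the adjusted permutation p was 0.19. Olfactory receptor genes had 13 of 387, against 1.59 (adjusted permutation p = 0.0040), led by OR2A42 (fold 4.18), then OR4F5, OR11H12 and OR11H2 (3.90 each), 3 of 6 tied genes taken by lower coordinate. The 13 genes rested on 12 peaks, since OR4K1 and OR4K5 share one, and many lie side by side. Against shifts along the gene order, which keep neighbours together without matching length, the ratio was 5.75 (adjusted permutation p = 0.013). In or within 2 Mb of a centromere band were 6 of the 13, OR11H12 and OR11H2 among them, and arm peaks alone gave 7 of 387 (4.40 times random lists, adjusted permutation p = 0.014, against 8.20 times with all peaks). No olfactory receptor had a summit among peaks with a −log10 q of 5 or more, or with a fold of 5 or more.

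The remaining lists did not pass the test. Members with a summit near an end were BDNF (fold 3.29) of 25 neuronal genes and PTPRC (4.39) of 18 markers of immune, endothelial and fibroblast cells. A list of zinc finger genes took every protein-coding symbol of ZNF followed by digits, without a check for a KRAB domain. Of its 477 members, ZNF479 (3.90), ZNF684 (3.41) and ZNF92 (3.41) had a summit near an end. No member had one among 21 telomere maintenance genes such as TERT and DKC1, 20 DNA damage response genes such as ATM and ATR, or 9 genes earlier tied to TRF2 outside telomeres, such as PDGFRB and HS3ST4. The same held for the ends of 33 heparan sulfate proteoglycan genes (GPC1, GPC2), 28 S100 and annexin genes (S100A1, S100A2), 16 microRNA processing genes (DROSHA, DGCR8) and 20 Wnt targets (AXIN2, LGR5). It held for 20 genes each of colon epithelium (CDX1, CDX2), epithelial to mesenchymal transition (VIM, CDH2) and p53 targets (CDKN1A, MDM2), for 21 immediate early genes (FOS, FOSB) and for 24 cell cycle genes (CCNA2, CCNB1). It held as well for 35 replication-dependent histones (H1-1, H1-2), 70 ribosomal proteins (RPL3, RPL4) and 29 respiratory chain genes (NDUFA1, NDUFA2). Lists of 6 to 70 genes were expected to hold fewer than 1 such gene, so a depletion was not detectable in them. Counting summits anywhere in the gene or within 3 kb, 2 of the 9 genes earlier tied to TRF2 had one, HS3ST4 (fold 7.43, −log10 q 10.4) and GPC6 (fold 3.41, −log10 q 0.811), as had 6 of the 33 heparan sulfate genes, and neither list passed the test (adjusted permutation p = 1.0).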

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

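Signals outside the primary chromosomes were followed up because the comparisons leave them out. Unplaced and unlocalized sequences carried 1955 peaks on 115 sequences, with a median fold of 4.23, and the 3 sequences with the most held 507 of them (25.9%). The mitochondrial genome carried 22 peaks, with a median fold of 1.56 over an input background of 74.5. With both libraries at the ceiling of 1 read per position and strand, the fold would be 1.76.

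All tests below were chosen after the result they bear on was seen, except the density ratios of 10q and 17q, which were set once the 8q pattern was known and before their values were computed. The centromeric excess held among strong peaks: 69.1% of primary-chromosome summits with a −log10 q of 5 or more lay in centromere bands, against 68.2% of all, which argues against noise from the loose p threshold. Collapsed repeat copies, with reads in proportion in both libraries, would raise the input as much as the immunoprecipitate. Yet 3095 centromeric peaks (20.4%) had the minimum input background, in 92.9 Mb, with a median fold of 4.39. On arms 2568 peaks had that background, in 2761 Mb, with a median fold of 3.41. These values argue against collapsed copies alone for those centromeric peaks. The other 79.6% had an input above the minimum, as extra copies would give, so collapsed copies stay open for them. At a like input background, the median fold was higher for centromeric than for arm peaks in 4 of 8 classes of background, which by number decides nothing. They included every class with a background up to 2, with 2568, 348 and 184 arm peaks (medians 4.39, 4.39 and 4.47 against 3.41, 3.76 and 4.09). The classes that went the other way lay between 2 and 20 and had only 31 to 59 arm peaks each. Binding of TRF2 to satellite DNA, the biological alternative that the design of immunoprecipitate against input could show, has no test here.

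The excess of arm peaks on parts of 8q, 10q and 17q may reflect copy number. Peaks were dense on 1q too (1.83 times the other arms), with no known gain here, but they differed in kind. On 1q the median pileup was 32 reads, 36.1% of peaks had the minimum background and 130 of 230 were strong. On 8q these values were 6 reads, 83.8% and 14 of 555, so 1q is no like case for 8q. Density was 5.05 times higher in the part of 8q known to be gained in HCT116 than in the rest of the arm (exact interval 3.27 to 8.23), 3.77 times on 10q (2.67 to 5.39) and 6.04 times on 17q (2.29 to 22.6). Extra copies would give this only where the background behind the peaks did not rise with them. On 10q and 17q the excess also did not begin at the edges of the named bands. If peaks otherwise spread evenly, a gain of even size is argued against on 10q and 17q, where the densest 5 Mb window held 44.2% and 49.5% of the peaks of the part (lower exact bounds, allowing for the choice among windows, 32.3% and 35.4%, each more than 2 times the window's share of length), but cannot be told apart on 8q, which was uneven by less (15.5%, bounds 11.2% and 20.7%, against 6.25% of the length). Many strong focal sites as the whole cause on 8q are argued against by the ratio of 0.989 among strong peaks, whose upper bound of 1.68 (2.43 without 1q) is below 5.46 for all peaks, while within the arms strong peaks in the gained part and the rest numbered 13 and 1 on 8q (ratio 2.58, exact interval 0.388 to 110; 7 of the 13 in TERF1), 14 and 1 on 10q (9 of the 14 in its last window) and 1 and 2 on 17q, so focal sites on 10q stay open. Whether the gain was alike in the input cannot be told apart: 83.8% of 8q peaks had the minimum background, against 74.5% on the other arms, but that minimum is genome-wide and hides input gains below it, and weak binding of TRF2 spread over these bands stays open.

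The clusters of peaks in TERF2 and TERF1 could come from DNA of these genes that is not chromosomal. For TERF2, extra copies in both libraries, such as a vector, would raise the input too. Of its summits 100% had an input background above the minimum (exact interval 66.4% to 100%), against 23.8% of the other arm peaks. Such an interval takes the 9 summits as independent, though they lie in 1 gene and near ones can share input reads. Copies in like proportion would raise the immunoprecipitate no more than the input, so they alone do not give the fold of 5.50 to 12.2 at these summits. For TERF1 the share was 37.5% (8.52% to 75.5%) against 23.9%, too few summits to decide by this share. Yet 5 of its 8 summits had the minimum input background. Copies in like proportion alone do not give the fold of 4.82 to 20.1 at TERF1 either. Intronless copies of TERF1, from a vector or from spliced transcripts, would also align to its pseudogenes: apart from TERF1P4 (fold 36.6), which prompted the test, 3 of 6 TERF1 pseudogenes carried a peak, TERF1P5 (17.6), TERF1P2 (12.2) and TERF1P3 (4.88), against 0.617% of 16853 others (Fisher's exact test, two-sided, p = 4.9e-06; on arms 1 of 3, the weak TERF1P3, against 0.366%, p = 0.011; exact one-sided p = 4.9e-05 with the region of each pseudogene kept). Binding of TRF2 at its own gene and at TERF1 remains open, since summits could not be placed on exons here.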

How the results depend on the processing

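Settings limited to arms, to strong arm peaks, to a q-value under 0.05, without 1q or with shifts along the gene order, and all settings for the 8q density, the centromeric share and the chromosome ends hit, were chosen after seeing the data. Of the main results' 55 alternative values, 36 kept direction and side of the threshold. The centromeric excess and the number of chromosome ends with a peak did so under every setting run. The number of peaks was 7288 at a −log10 q of 5 or more, 6115 at a fold of 5 or more and 3378 on arms, by construction. The gene-end ratio turned to 1.13 among strong arm peaks, the chromosome-end ratio to 0.878 within 500 kb, and the miRNA ratio to 0.692 on arms and 1.18 among strong arm peaks; the cause was not tested, beyond the removal of centromeric peaks in the arm settings. Chromosome 13 had 18.5 peaks per Mb at a −log10 q of 5 or more, 15.6 at a fold of 5 or more, 33.7 at a q-value under 0.05 and 1.11 on its long arm. The 8q ratio was 0.989 at a −log10 q of 5 or more, 1.34 at a fold of 5 or more and 1.42 among strong peaks without 1q. Of 8 title loci, 2 had a peak, 4 within 50 kb and 1 at a −log10 q of 5 or more. Lists passing the test fell from 2 to 1 at a −log10 q of 5 or more, to 1 at a fold of 5 or more (shelterin in both) and to 1 with summits anywhere in the gene (olfactory receptors); the ratio to random lists was then 0.0 for olfactory receptors in the strict settings, where fewer peaks remain, and 12.5 for shelterin in the last. GC matching, telomere-repeat, G-quadruplex and motif alternatives were not run, as no genome sequence was used. No paired analysis was possible because each group had 1 library and no test compared samples. Depth limits weak peaks: at the minimum background the list begins at 5 reads.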

Other observations

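Genes and loci in this part were picked after their values were seen. Summits of a protein-coding gene are counted in its span and within 3 kb of it. ENAH, an actin regulator gene on chromosome 1, had 9 summits (best fold 7.32, 7 of them with a −log10 q of 5 or more), and its pseudogene ENAHP1 on chromosome 3 carried 2 peaks (best fold 4.88). NFYA, a subunit gene of the CCAAT-binding factor NF-Y, had 3 strong summits (best fold 9.87), in a span it shares with OARD1, while its pseudogene NFYAP1 had no peak. DUX4 at the end of 4q had 4 strong summits of low fold (best 2.76). Apart from these, TERF2 and TERF1, no protein-coding gene had more than 2 strong arm summits.

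On chromosome 2 a peak from 113603018 to 113603093 (fold 5.87, −log10 q 8.16, 20 reads) lay in DDX11L2, a pseudogene of a subtelomeric family, in the region where 2 ancestral chromosomes are known to have fused end to end. It is the peak listed for LOC124907874. Peaks of high fold on arms with no input excess also lay in SEMA5A (21.5), SOX5 (17.6) and LRRC4C (16.1), each inside a long gene.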
